A study of Mus musculus with 108 samples.

How the data were processed

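Single acinar cells, the enzyme-secreting cells of the exocrine pancreas, were collected from untreated male C57BL/6 mice aged 12 weeks. Per the labels' protocols, the pancreas was digested with collagenase, filtered to remove islets and treated with Accutase, single cells were taken up into lysis buffer, and cDNA was made and amplified by a modified SMART-seq2 procedure that has no molecular identifiers. Each of the 108 samples was 1 cell. The labels placed them all in 1 group and named no animal, day or plate, so the group counted as 1 sample, cells were not treated as replicates, and no p-value or standard error was computed. SDs and ranges over cells describe the spread between cells.

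The deposited table held TPM (a read share corrected for transcript length) for 45195 Ensembl gene rows, rounded to 2 decimals. The unit was taken from the values, which summed to about 1000000 in most cells. STAR 2.4.2a, RSEM 1.2.21, edgeR and the mm10 build are named per the submitters' processing notes, with no role or order given. Each cell's column was matched by its cell number, and 44548 rows were matched to gene symbols. Of all rows, 25226 were 0 in every cell. Mitochondrially encoded genes (13 names) and spike-in rows were not analysed here. TPM keep no read depth, so the depth of each cell in reads is unknown and detection could not be brought to a common depth. RSEM shares reads among near-identical transcripts, so values of the trypsinogen, amylase and other multi-copy families are uncertain. Amy2a2, Amy2a3 and Amy2a4, for example, carried identical values. Coordinates are from GENCODE release M21 on GRCm38, the assembly also called mm10, and are 1-based spans of whole genes.

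A gene counted as detected at or above 1 TPM. Shares of cells carry exact (Clopper-Pearson) 95% binomial intervals, which cover counting error only. For 0 of 108 cells the limit of 3 cells, or 2.78%, is given. Genes detected in at least 10% of cells (11 cells, 7227 genes) entered all tests of variation. The squared coefficient of variation (CV) over cells was set against mean TPM with a lowess trend on log10 scales (span 0.3), and a gene was called variable at or above 2 times the trend. Co-variation of a list was the median Spearman correlation over cells of all pairs of its members, computed on log2(TPM + 1). It was placed among 10000 random lists of the same size, each member being replaced by 1 of the 100 genes nearest in mean expression. A list stood apart at or above the 97.5th percentile. Scores of lists were mean z-scores of log2(TPM + 1), and pairs of scores were compared with pairs of random lists. For the digestive enzymes no genes of similar mean exist, so their percentile was withheld and they were left out of the pairs. That choice was made after the values were seen. Cells were clustered by Ward linkage on 10 principal components of the variable genes, with 2 to 8 clusters chosen by mean silhouette width. No doublet caller was run, and no cell was left out.

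The gene lists were fixed before the data were examined. They covered digestive enzymes, acinar transcription factors, proliferation, progenitor genes, ER chaperones and the unfolded protein response, immediate-early and heat shock genes, Reg and acute-phase genes, interferon-response genes, ribosomal proteins, the respiratory chain, mitochondrially encoded genes, cholesterol and lipid synthesis, amino acid synthesis and transport, autophagy and lysosome, and a check of sex. Markers of acinar, ductal, endocrine, stellate, endothelial, macrophage, lymphocyte, erythrocyte, adipocyte and mesothelial cells were also fixed. Named genes followed a rule set at the same time. It took up to 6 examples of each list (the 3 of highest mean and the 3 of highest squared CV over the trend), the 20 most variable genes among those in at least 25% of cells, the 10 of highest mean, and the 10 highest and 5 lowest correlations with Stmn1. It also took 5 genes for each cluster, and Stmn1, Mki67, Ptf1a, Bhlha15, Sox9, Krt19, Ins2 and Xist. Other genes named were chosen after their values were seen.

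In 21 cells, numbered 92 to 113, the deposited values summed to less than 999900, and they are called short-total cells. The other 87 are called full-total cells. They were also divided after cell 48, a bound chosen after the Reg scores were seen. Results were recomputed within each set, with each gene taken as the difference between cells next to each other in cell number (lists and pairs only), and with other pseudocounts, scalings, detection levels, filters and clustering settings. The functions were tested on simulated data made with the real gene means. Simulated genes varied independently apart from what was planted, with no excess of zeros and no variation shared by all genes of a cell. The simulations therefore do not check the list and pair comparisons where random lists already co-vary, as they did here. Of 200 genes given 4 times the trend's squared CV, 81.0% were called variable, as were 4.51% of the other genes (7227 genes simulated in all). A simulated list of 20 genes with a shared factor reached the 100th percentile, and 0 of 18 lists without a shared factor reached the 97.5th. A linked pair of simulated lists also reached the 100th percentile, but 2 of 14 unlinked pairs lay past the 2.5th or 97.5th. With 14 cells shifted in part of 800 simulated genes, clustering recovered them with an adjusted Rand index of 1. A simulated single population was still split into 7 clusters, at a silhouette width of 0.0718. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6, scikit-learn 1.9.0 and matplotlib 3.10.9.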

Results

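The transcriptomes of single acinar cells from the pancreas of untreated adult male mice were measured, to describe how far acinar cells of the normal gland differ from one another. All cells formed 1 group. A median of 4156 genes per cell was detected at or above 1 TPM (mean 4180 ± 494, SD over all cells), from 2624 to 6946, the latter in cell 40. The deposited values summed to between 788380 and 990520 TPM in 21 cells, the short-total cells, and to 1000000 within rounding in the other 87, the full-total cells. Short-total cells had a median of 3939 genes detected and full-total cells 4224. There were no replicates of the group, so values are given with their spread between cells.

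Digestive enzymes and zymogen granule proteins filled most of each cell's transcriptome. The 40 measured members of the list took a mean of 88.8% of the TPM (SD 2.39 over cells, range 75.4% to 93.4%), and 38 of them were detected in every cell. Prss2, an anionic trypsinogen, had the highest mean of all genes at 102391 ± 10953 TPM. It was followed by Ctrb1, a chymotrypsinogen, at 100168 ± 16740 TPM, the amylase Amy2a1 at 77071 ± 20359 TPM, the elastase Cela2a at 71040 ± 7289 TPM and Clps, the colipase, at 68163 ± 10065 TPM. Cela1, Ctrl, Try4, Pnlip and Try5 completed the 10 highest means, and Pnlip, the pancreatic lipase, stood at 36466 ± 4737 TPM. The CV between cells was 0.103 for Cela2a, 0.107 for Prss2 and 0.130 for Pnlip, so these enzymes were nearly even across cells in TPM. The SDs of Amy2a1 and Ctrb1 were larger relative to their means. Since the enzymes fill most of a fixed total, TPM leave little room for them to vary as a set. The CV reached 0.475 for Try5 and 2.01 for Prss3, members of the trypsinogen family whose near-identical sequences make their separate values uncertain. As a share of each cell's own deposited total, the enzymes took a median of 91.4% in short-total cells and 88.8% in full-total cells. On the deposited log2(TPM + 1) scale they were lower in short-total cells, by a median of -0.081 (28 of 37 members lower), against -0.15 over all tested genes.

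All 10 acinar markers were detected in every cell, at levels that differed between cells. Ptf1a and Bhlha15, transcription factors of acinar differentiation, averaged 12.3 ± 7.31 TPM (range 1.71 to 43.2) and 13.2 ± 6.13 TPM, and Rbpjl, a partner of Ptf1a, averaged 35.3 ± 12.9 TPM. Of the ductal markers, the mucin Muc1 and the secreted chaperone Clu were detected in every cell, at means of 25.2 and 200.2 TPM, and Epcam was detected in 86 cells. Krt19, a keratin of duct cells, was detected in 72 cells (66.7%, interval 56.9% to 75.4%), at a median of 1.72 TPM, and Sox9 in 28 cells at a highest value of 6.14 TPM. Ins2, the beta cell insulin gene, reached 1 TPM in 4 cells (3.70%, interval 1.02% to 9.21%) and never exceeded 7.92 TPM. Of the 14 endocrine markers, at most 2 were detected in any cell. Lymphocyte markers (13 measured) were detected in 0 cells, which allows a share of up to 2.78%. The macrophage list was represented mainly by C1qa, in 16 cells, and no cell held 3 or more of its 13 markers. For erythrocyte, adipocyte and mesothelial markers, at most 1 was detected in any cell apart from Krt19, which the mesothelial list shares with the ductal list.

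Xist, the female-specific RNA of the inactive X chromosome, was detected in 0 cells, and the Y-linked genes Eif2s3y, Ddx3y and Uty in 77, 37 and 12, matching the male label. Only 1 cell held 3 or more endothelial markers. Cell 40 had 8 of the 11, with Plvap at 25.4 TPM, Egfl7 at 22.7 TPM and Pecam1 at 11.5 TPM, and it also held 3 stellate markers. Cell 96 held 5 stellate or fibroblast markers, led by Dcn at 12.6 TPM, a proteoglycan of fibroblasts. These genes were chosen after their values were seen. At least 3 ductal markers, leaving out those present in over 54 cells, were found in 7 cells.

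Stmn1, which encodes the microtubule-destabilising protein stathmin (chromosome 4, 134468320 to 134473843), was nearly binary across the cells. It was detected in 29 cells (26.9%, interval 18.8% to 36.2%). In cells 40 and 31 it reached 108.72 and 107.55 TPM, whereas the highest of the other cells held 4.65 TPM and the 27 of them with Stmn1 detected had a median of 1.90 TPM. The same pair of cells carried the cell cycle genes. Of 38 proliferation genes, 29 were higher in cell 31, and 36 in cell 40, than in any cell outside this pair, with 29 in common, and 20 were detected in none of the other cells. Mki67, the Ki-67 proliferation antigen, was detected in 2 cells only (1.85%, interval 0.225% to 6.53%), at 9.57 TPM in cell 40 and 1.55 TPM in cell 31. Tuba1b reached 218.78 and 120.85 TPM in cells 40 and 31 against at most 8.08 TPM elsewhere. Rrm2, a subunit of ribonucleotide reductase, reached 68.74 and 18.16 TPM against at most 2.79 TPM elsewhere, and the histone variant H2afz 318.32 and 318.66 TPM against at most 68.05 TPM. Among the other cells, a median of 4 and a maximum of 11 proliferation genes were detected, and none of the 27 with Stmn1 had more than 9. Pcna (92 cells), Tuba1b (90 cells) and Tubb5 (79 cells) were nevertheless present at low level in most cells. The count of cells with Stmn1 depended on the detection level, with 2 cells at 10 TPM and 52 cells above 0.

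**Figure D1:**
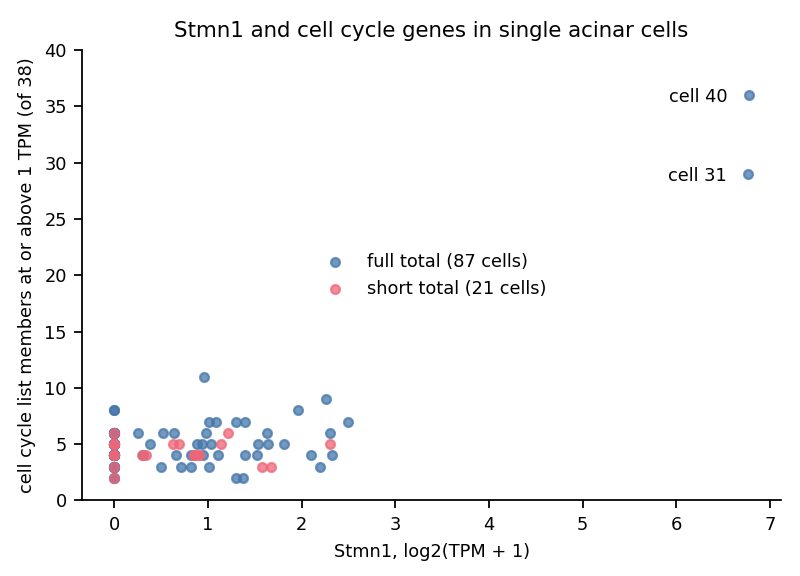
Each point is 1 cell, placed by Stmn1 as log2(TPM + 1) on the horizontal axis and by the number of 38 cell cycle genes at or above 1 TPM on the vertical axis, with short-total cells in red and full-total cells in blue. Cells 40 and 31 stand apart at 36 and 29 genes, and no other cell exceeds 11.

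Of the progenitor genes, 26 were measured and 10 were detected in at least 10% of cells. Cd24a, a surface glycoprotein, was detected in every cell at 31.4 ± 12.4 TPM, and Aldh1a1 and the membrane protein Prom1 in 96.3% of cells each, at 4.16 ± 2.69 and 3.79 ± 2.24 TPM. Hes1, a Notch target, was detected in 33 cells and Bmi1 in 21, while 9 members were detected in no cell. Besides Stmn1, Hes1 was the only variable member, at 3.16 times the trend.

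Of the 7227 genes tested, 867 varied at least 2 times more than the trend for their mean. Gm5771, Prss3 and Gm10334, all of the trypsinogen-like family on chromosome 6, were 108.7, 68.7 and 27.5 times above the trend in squared CV, and each peaked in cell 37 (Gm5771 at 2689 TPM against a median of 45.1 TPM). Reg2, a secreted lectin-like protein of the regenerating family, was 95 times above it, with a median of 51.9 TPM and a highest value of 9527 TPM in cell 51. Reg3b and Reg3g followed at 40.8 and 32.2 times. Stmn1, Tuba1b and Cks2 were 62.4, 58.7 and 27 times above the trend, but at 1.90, 1.06 and 1.97 times without cells 31 and 40. The stress-response factor Atf3 and the RNA-decay factor Zfp36 were 26.9 and 25.8 times above it. The remaining members of the 20 most variable genes were non-coding RNAs (Rpph1, Snord118), the zinc finger gene Zfp950 and 6 predicted genes, Gm26870, Gm10800, Gm25745, Gm44364, Gm21738 and Gm12918. Of the list members detected in at least 10% of cells, 23 of 27 immediate-early and heat shock genes were variable, all 7 Reg and acute-phase genes, 10 of 39 digestive enzymes, 9 of 28 ER chaperone genes and 7 of 8 proliferation genes. In contrast, 0 of 12 acinar transcription factors, 0 of 33 respiratory chain genes and 1 of 44 ribosomal protein genes were. The proliferation count includes cells 31 and 40 and was not recomputed without them. Its member Tuba1b, at 1.06 times the trend without that pair, was then no longer variable. In random sets of 54 cells, 902 and 874 genes were called, with 490 in common, so which genes were called depended on the cells sampled.

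**Figure D2:**
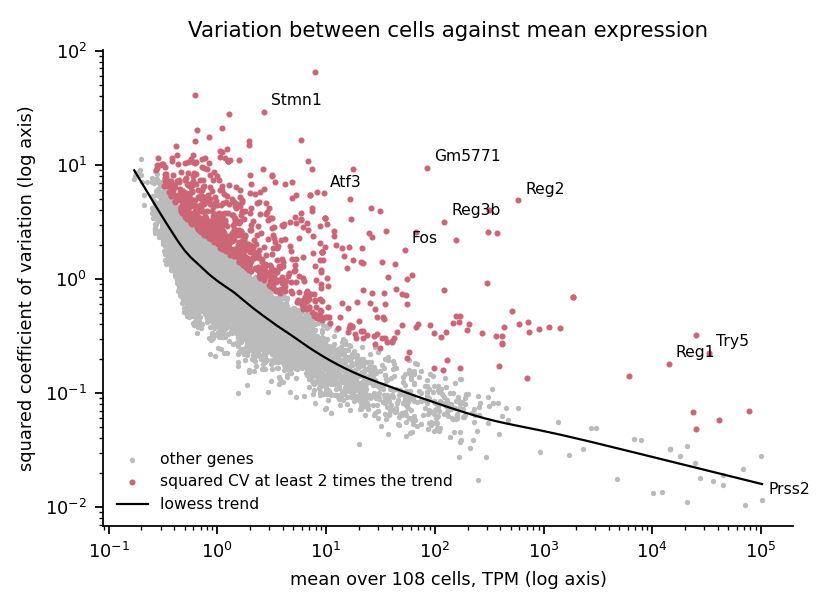
Each point is 1 of 7227 genes, with mean TPM over all cells on the horizontal axis and squared CV on the vertical axis, both on log scales, the black line being the lowess trend. The 867 genes at least 2 times above the trend are red, among them Reg2, Gm5771, Stmn1 and Atf3, while the abundant enzyme Prss2 lies below the line.

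Several fixed lists varied together from cell to cell. The Reg and acute-phase list had the highest median correlation between members, 0.67 over 7 genes against 0.11 for random lists. Its most abundant member Reg1 averaged 14162 ± 6020 TPM and Nupr1, a stress-induced chromatin protein, 707 ± 261 TPM. Ribosomal protein genes (44 members, led by Rpl32, Rplp1 and Rpl13) had a median correlation of 0.62 against 0.15. ER chaperone and unfolded protein response genes (28 members) stood at 0.32 against 0.11. They included Pdia2, a pancreatic disulfide isomerase at 930 ± 163 TPM, and the stress-induced genes Chac1, Ddit3 and Herpud1, which all peaked in cell 83. Immediate-early and heat shock genes (27 members) stood at 0.32 against 0.074, with Fos, a transcription factor induced within minutes of stimulation, at 52.9 ± 71 TPM and the chaperones Hspa8 and Hsp90aa1 at 55.6 ± 43.1 and 43 ± 50.1 TPM. These 4 lists lay at the 100th percentile of random lists.

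Weaker co-variation was found for the other lists. The respiratory chain genes, such as Atp5g1 and Ndufa1, had a median correlation of 0.26 and the amino acid genes, such as Gatm, Asns and Phgdh, 0.24, both at the 100th percentile. Interferon-response genes (8 members, among them Ifi27, H2-K1 and B2m) stood at 0.19, proliferation genes at 0.17 and acinar transcription factors, led by Xbp1, at 0.16, and each exceeded the 99th percentile. With scaling without the digestive enzymes, the interferon list fell to 0.136, at the 96.4th percentile. Cholesterol and lipid genes, such as Fdps and Insig1, stood at 0.14 and autophagy and lysosome genes, such as Gabarap, Ctsl and Ctsd, also at 0.14, but the latter only at the 97.9th percentile of random lists and at the 87.7th in full-total cells alone. Progenitor genes stood at 0.12, and at 0.0024 once each gene was taken as a residual on the number of genes detected. The digestive enzymes had a median correlation of 0.0072, which decides nothing about shared variation, since genes that fill most of a fixed total must balance one another. With median-of-ratios scaling, the respiratory chain list fell to 0.070 and the amino acid list to 0.12, ER chaperones to 0.15, acinar transcription factors to 0.063 and autophagy genes to 0.032, while random lists fell to near 0. The Reg, ribosomal and immediate-early lists stayed at 0.65, 0.54 and 0.32.

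Taken as differences between cells next to each other in cell number, the Reg list fell to 0.24, at the 97.3rd percentile of random lists. It stood at 0.29 (99.89th percentile) within cells 1 to 48 and at 0.27 (97.1st percentile) within cells 49 to 91. Ribosomal proteins stayed at 0.66, immediate-early genes at 0.33 and ER chaperones at 0.29. Within the 87 full-total cells the median correlation was 0.66 for the Reg list, 0.63 for ribosomal proteins, 0.29 for ER chaperones and 0.36 for immediate-early genes. Within the 21 short-total cells it was 0.65 for ribosomal proteins, 0.27 for ER chaperones and 0.29 for immediate-early genes. The Reg list, at 0.13, lay only at the 71.8th percentile there (71.35th in a second draw of random lists). Proliferation, progenitor, respiratory chain, cholesterol and amino acid genes also fell out of the top 2.5% of random lists in those 21 cells.

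**Figure D3:**
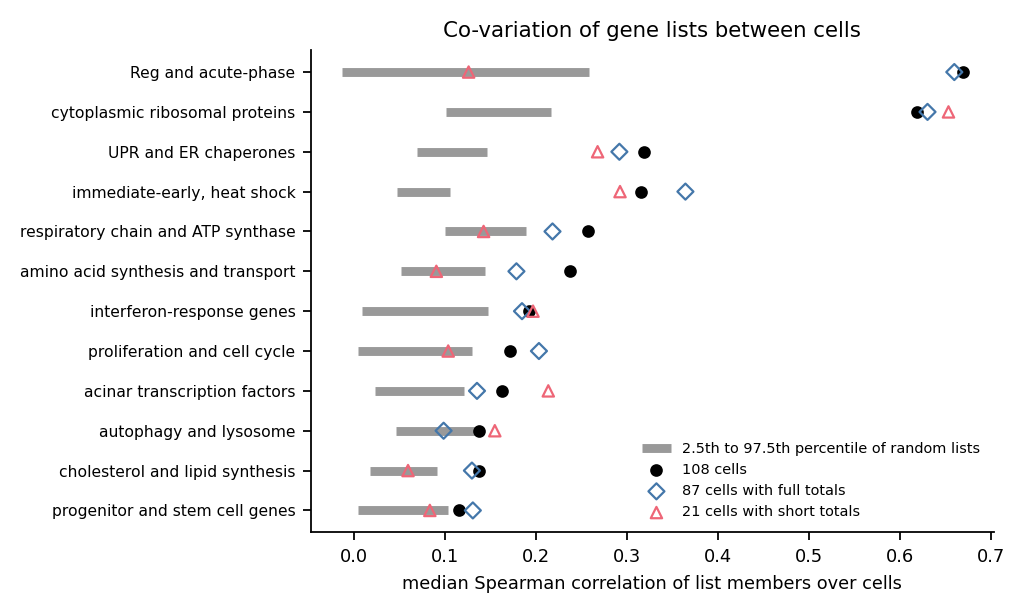
Each row is 1 gene list, with the median Spearman correlation of its members over cells on the horizontal axis, for all cells (black), 87 full-total cells (blue diamonds) and 21 short-total cells (red triangles), and the grey bar spanning the middle 95% of 10000 random matched lists over all cells. The Reg list falls from 0.66 in the full-total cells to 0.13 in the short-total cells, while ribosomal proteins stay at 0.63 and 0.65.

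Scores of many list pairs were correlated, though often less than those of random list pairs. Scores of ER chaperones and amino acid genes rose together over the cells (Spearman 0.72, Pearson 0.68, and 0.66 without the 2 cells farthest from the median), with 0.59 in full-total and 0.48 in short-total cells. Random list pairs had a median of 0.72, so this pair did not stand apart. Acinar transcription factors and amino acid genes had a Spearman correlation of 0.67 (Pearson 0.66, and 0.65 without the 2 farthest cells), with 0.64 and 0.67 in the full-total and short-total cells. Random pairs had a median of 0.54, which put this pair at the 96.1st percentile, and it entered the top 2.5% in 6 of 12 other settings. Reg and ribosomal protein scores were at -0.14 (Pearson -0.11, and -0.13 without the 2 farthest cells) against 0.68 for random pairs, with -0.24 in full-total and 0.21 in short-total cells. ER chaperones and immediate-early genes were at 0.07 (Pearson 0.19, and 0.17 without the 2 farthest cells), with 0.28 and 0.08 in the 2 sets. Of 66 pairs, 30 lay at or below the 2.5th percentile of random pairs and 1 in the top 2.5%, the pair of cholesterol and amino acid genes. With median-of-ratios scaling, only 7 pairs lay at or below the 2.5th percentile. Random pairs had median correlations from 0.29 to 0.82, so a low percentile does not mean that 2 scores were unrelated. ER chaperone and respiratory chain scores, for example, lay at the 0th percentile with a Spearman correlation of 0.51.

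ER chaperone genes were lower, and immediate-early genes higher, in the 21 short-total cells than in the 87 full-total cells. The ER chaperone list differed by a median of -0.51 on the log2(TPM + 1) scale (short-total minus full-total, 24 of 28 members lower), below all random matched lists, and Hspa5, the ER chaperone BiP, had medians of 51 and 107.3 TPM. The immediate-early list differed by 0.20 (20 of 27 members higher), above all random lists. Fos and Atf3 rose most, with medians of 56.9 and 14.6 TPM and of 5.30 and 0.14 TPM. Of the heat shock genes on the list, Hspa1a (-1.03), Hspa8 (-0.44) and Hspa1b (-0.20) were lower in short-total cells. Hsp90aa1 (0.20), Dnajb1 (0.16) and Hspb1 (0.04) were slightly higher. The whole list differed by 0.48 from the 47 full-total cells numbered 1 to 48. From the 40 numbered 49 to 91 it differed by 0.0091 (15 of 27 members higher), still at the 99.98th percentile of random lists, since most genes were lower in short-total cells. The ER chaperone list differed by -0.48 and -0.51 from these sets of cells.

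Reg genes were high in the full-total cells numbered 49 to 91 and lower in the others. The Reg list differed by -1.36 between short-total and full-total cells (6 of 7 members lower), but only cells 49 to 91 carried this difference. Within the full-total cells the Reg score rose with cell number (Spearman 0.71, against -0.25 for random lists), where ER chaperones and immediate-early genes also rose (0.19 against -0.29 and 0.18 against -0.23). The Reg score was above 0 in 38 of the 40 cells numbered 49 to 91 and in 7 of the 47 numbered 1 to 48. Reg2 had a median of 982 TPM in cells 49 to 91, against 16.2 TPM in cells 1 to 48 and 15.1 TPM in short-total cells. For Reg3b these medians were 172.6, 7.26 and 7.62 TPM, and for Reg1 18991, 10658 and 9432 TPM. Short-total cells differed by -0.22 in the Reg list from cells 1 to 48, at the 51.4th percentile of random lists. The labels name no animal or day, so these differences cannot be told apart from differences between mice. Hspa5 and the division at cell 48 were chosen after the values were seen.

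**Figure D4:**
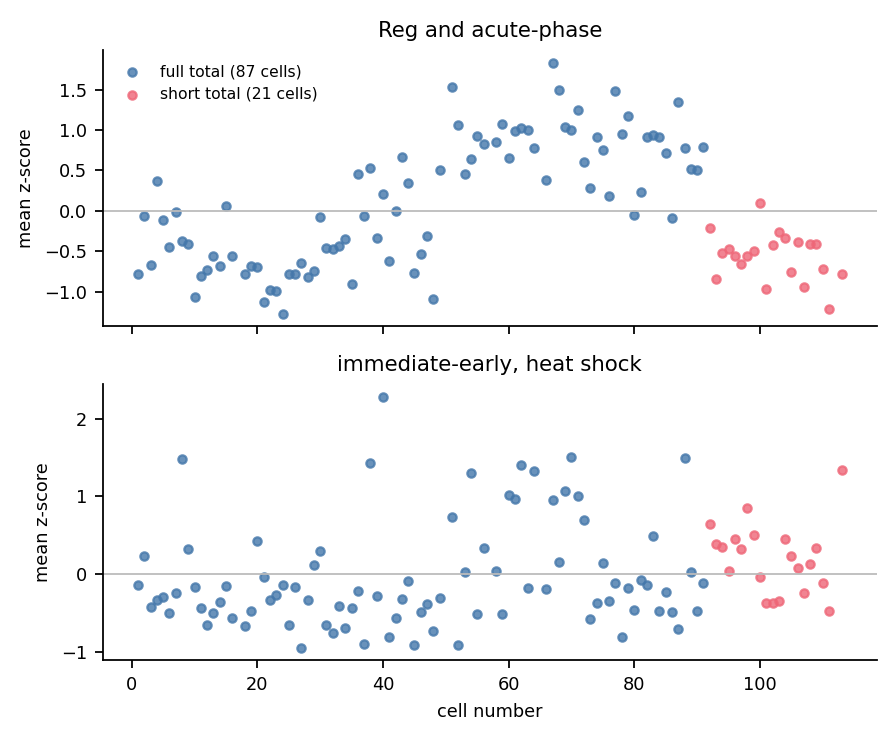
Each point is 1 cell, placed by cell number on the horizontal axis and by its mean z-score of log2(TPM + 1) on the vertical axis, over the Reg and acute-phase list (upper panel) and the immediate-early list (lower panel), with short-total cells in red and full-total cells in blue. High Reg scores are gathered in cells 49 to 91, while immediate-early scores are spread more widely, though not evenly, over the cell numbers. Above 0 lie 8 of 47 immediate-early scores in cells 1 to 48 and 19 of 40 in cells 49 to 91. In short-total cells 14 of 21 lie above 0. Many of the high immediate-early scores are in cells 60 to 71.

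Genes ranked by correlation with Stmn1 did not form a stable set. Over 7226 genes the highest Spearman correlations included those of Ecd (0.37), the replication licensing inhibitor Gmnn (0.35), Atp5s (0.35), the histone chaperone Anp32b (0.34), Dtnbp1, Rab3il1, Slc16a13, Pcolce and Gpn3. The lowest were those of the pseudogene Rps6-ps4 (-0.36), Cyp2c70, Atxn2l, Hectd3 and Mrpl37. The highest and lowest values were of similar size. What unrelated genes would reach in so long a ranking was not computed, so the ranking alone does not tie these genes to Stmn1. Pearson's r with Stmn1 was 0.51 for Gmnn and 0.58 for Anp32b, and 0.31 and 0.32 without cells 31 and 40. For Ecd it was 0.37, and 0.40 without them. Within full-total cells Spearman's coefficient was 0.49 for Anp32b, 0.45 for Gmnn and 0.38 for Ecd, and within short-total cells -0.37, -0.05 and 0.35. Of the 10 highest genes, 2 were again among the highest 10 after residuals on genes detected and 0 when only cells with Stmn1 were used. Most of them were kept without cells 31 and 40.

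Clustering separated 94 cells (cluster 1) from 14 cells (cluster 2, 13%, interval 7.27% to 20.8%) at a silhouette width of 0.245. Cells of both clusters carried all 10 acinar markers. Cluster 2 was defined by Hist1h2ap, Zfp36, Stmn1, Atf3 and Tuba1b, and held cells 31 and 40, which set the means of several of these genes, while Zfp36 and Atf3 were detected in 13 of its cells. Cluster 1 was defined by Gm11518, Zfp950, Gm5409, 1810007D17Rik and Gm10039, at low means. The median number of genes detected was 4080 in cluster 1 and 4710.5 in cluster 2, and cluster 2 held 0 short-total cells. Cluster 2 held cells 8, 31, 38, 40, 51, 54, 56, 61, 62, 64, 67, 69, 70 and 71. Most of them were thus numbered 51 to 71, and none was numbered above 71. The labels name no animal or batch, so the cluster cannot be told apart from such a difference. All 7 changes of clustering settings fixed beforehand moved the partition, with adjusted Rand indices of 0.065 to 0.55 against it, so membership was not stable. It kept an index of 0.77 in full-total cells alone and of 0.71 without small RNAs, repeats and predicted genes.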

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

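The 21 short-total cells lacked part of the expected 1000000 TPM, a signal that lies outside the rows analysed here. The missing share had a median of 3.32% and ranged from 0.948% to 21.2%, against at most 0.00175% in the other 87 cells. The labels say that 24 cells received spike-in RNA without naming them, so whether these 21 are among them is unknown. The same cells, a run of the highest cell numbers, had lower ER chaperone genes, and immediate-early genes that were higher by 0.48 than in cells 1 to 48 and by 0.0091 than in cells 49 to 91. Their Reg genes were lower than in cells 49 to 91, but at the 51.4th percentile of random lists against cells 1 to 48, so low Reg genes were not particular to these cells. These comparisons by cell number and the rescaling below were added after seeing the data.

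A smaller number of genes detected was weighed first. After each gene was taken as a residual on genes detected, the ER chaperone list still lay at the 0th percentile of random matched lists, the Reg list also at the 0th, and the immediate-early list at the 100th. The ER chaperone difference shrank from -0.51 to -0.31, so part of it may go with genes detected, while the immediate-early difference grew from 0.20 to 0.51. Rescaling every cell to 1000000 left the ER chaperone difference at -0.43, the Reg difference at -1.34 and the immediate-early difference at 0.28. Rescaling multiplies all genes of a cell by 1 factor, which is small at a median missing share of 3.32%. A large change could therefore not have followed. The values show only that the lower scale itself does not make up these differences. They cannot speak on whatever fills the missing TPM. A difference in animal, collection day or library batch stays open, since the labels name none of them, and no biological explanation was tested.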

How the results depend on the processing

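TPM carry no read depth, so thinning to a common depth was not run, and neither was a split by spike-in rows, which were not analysed here. Subsets and rescaling by short totals, sets without cells 31 or 40, and differences between successive cells were added after seeing the data. Detection above 0 and at 10 TPM gave medians of 8086 and 792.5 genes per cell, 30 and 1 cells with 3 markers of another type (8 at 1 TPM), 52 and 2 cells with Stmn1, and 4 and 0 cells with Mki67 (0 without cells 31 and 40). The enzyme share was 55% without trypsin and amylase copies. Variable genes numbered 2946 without a filter, 1568 at 1.5 times and 413 at 3 times the trend, and 902 and 874 in the random sets, which shared 490. Other pseudocounts leave ranks and so list co-variation unchanged. Of 120 other recomputed list co-variations, all but 15 weaker and 1 reversed kept their side of the top 2.5% of random lists. The weaker were progenitor genes at 0.0954 and interferon genes at 0.136 (scaling without enzymes), autophagy genes at 0.0386 (residuals on genes detected), 0.0891 (without the lowest 10% of cells), 0.0983 (87 full-total cells), 0.124 (without cells 31 and 40) and 0.117 (rescaled to 1000000), progenitor genes at 0.0848 without cells 31 and 40, and Reg genes at 0.239 with differences between successive cells. In the 21 short-total cells they were proliferation 0.103, progenitor 0.0831, Reg 0.126, respiratory chain 0.142, cholesterol 0.0592 and amino acid 0.0903. Progenitor genes fell to 0.0024 with residuals, below the random 0.0028. Pairs at or below the 2.5th percentile fell from 30 to 7 with median-of-ratios scaling and to 11 in the 21 cells. With that scaling, immediate-early and ribosomal scores (-0.13) and ER chaperone and Reg scores (0.23) came to lie just above random pairs. Of the 10 genes highest with Stmn1, 2 were shared with residuals, 0 in cells with Stmn1 and 4 without the lowest 10% of cells, but most without cells 31 and 40. Adjusted Rand indices of the clusters were 0.283 and 0.254 with 5 and 20 components, 0.419 with k-means, 0.142 with average linkage, 0.552 without enzymes among the variable genes, 0.065 with residuals and 0.288 with scaling without enzymes. Stricter thresholds and shorter lists give fewer calls by construction. Smaller sets of cells need not, since the random sets gave 902 and 874 variable genes against 867 over all cells. Otherwise the cause of these changes was not tested.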

Other observations

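The ductal transcripts Spp1 and Tm4sf4 were high in a few cells. Spp1, the secreted phosphoprotein osteopontin, was detected in 10 cells, at 343.6, 293.9, 293.7, 245.8 and 164.2 TPM in cells 15, 29, 40, 56 and 75, and at no more than 6.14 TPM in the others. The same 5 cells held the 5 highest values of Tm4sf4, a tetraspanin-like membrane protein, from 9.03 TPM in cell 56 to 21.7 TPM in cell 29. All 10 acinar markers were detected in each of them. The 5 cells were noticed in the data and whether they were acinar cells with duct genes or wells with material of another cell was not tested.

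The tests on cells 31 and 40, on neighbouring or divided cell numbers and on full-total cells alone were added after seeing the data. Cells 31 and 40 shared the cell cycle genes but not their surroundings. Cell 31 ranked 40 by genes detected and had at most 1 marker of any non-acinar list, which argues against RNA of another cell type and against a fuller library as the cause there. A second acinar cell in the well would leave no such marker and stays open. Cell 40 ranked 1 by genes detected and held 8 endothelial markers, with 51.4 TPM of Fabp4, so its cell cycle genes may in part come from another cell in the well. A candidate reading is therefore that 1 cell, cell 31, was an acinar cell in the cell cycle, a hypothesis that rests on a single cell. Its acinar transcription factor score of -0.96 was among the lowest, and its Ptf1a, at 5.02 TPM, ranked 91 from the top. Acinar markers were detected in every cell, cell 40 included, so their detection does not help to decide.

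Co-variation of Reg genes and of immediate-early genes was weighed against sets of cells. With each gene taken as the difference between cells next to each other in cell number, the Reg list fell from a median correlation of 0.67 to 0.24, at the 97.32nd percentile of random lists, and it stood at 0.29 within cells 1 to 48 (99.89th percentile), 0.27 within cells 49 to 91 (97.09th) and 0.13 within short-total cells (71.35th). A difference between runs of cell numbers, as from an animal or a batch, may therefore account for much of it, and its 100th percentile in the 87 full-total cells alone does not argue against this, since those cells are themselves divided by cell number. Sharing of reads between near-identical Reg genes would tie Reg3b to Reg3g. Over all cells, Reg1, Reg2 and Reg3d had a median correlation of 0.633 with that pair. The level exceeded by 2.5% of such medians from random genes was 0.333. All of these Reg genes had higher medians in cells 49 to 91 than in the other runs, which alone can raise this correlation. The value therefore cannot decide on read sharing, which stays open. What separates the runs is not in the labels, and no biological explanation was tested.

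Immediate-early genes kept the 100th percentile with differences between such neighbouring cells (median correlation 0.327), in the 87 full-total cells alone and after residuals on genes detected, which argues against each of these as the whole cause. The median score of the list still differed between runs, at -0.33 in cells 1 to 48, -0.091 in cells 49 to 91 and 0.24 in short-total cells. Within these runs its median correlation was 0.30, 0.43 and 0.29, each at the 100th percentile. A difference between runs may therefore be part of the co-variation, though some remained within each run. Handling during digestion could produce co-variation of these genes, and whether it did was not tested.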
